A study of Sus scrofa with 12 samples.

How the data were processed

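Total RNA from portions of 3 to 5 g of semimembranosus muscle was labelled with biotin and hybridised to one-colour Affymetrix porcine arrays, per the labels' protocols. The 3 pigs were stunned with CO2 at 87%, and the same muscle of each was sampled at 20 min, 2 h, 6 h and 24 h, per the series' design text. The deposited values are log2 intensities per probe set, made with RMA in the affy package per the submitters' processing notes; RMA corrects background, quantile-normalises and summarises the probes of a set. The versions and parameters of those tools are not given in the sources used here. The sorted values of each array lay within 0.126 of the mean sorted values, so the arrays share 1 distribution, and a change that shifted all transcripts alike would not show in these values. Signal over background per probe is not given in the table used, and the number of arrays limits the precision.

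Of 24123 probe sets, 124 controls were left out of the tests and 23999 were tested without a filter on level. Gene names came from the 2016 platform annotation, which can be old. It gave 10099 probe sets 1 symbol, 198 several and 13826 none here; genes were named from sets with 1 symbol only. The symbol matched the Sscrofa11.1 RefSeq gene table through its gene ID in 9989 cases. No coordinates are given because no build is named for the array. For gene lists, each of 6765 genes was represented by its probe set with the highest mean over the 12 arrays.

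Groups and pig numbers were taken from the sample titles. Tests used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. One linear model of all 12 arrays held the 4 times and pig as a fixed block, with default empirical Bayes settings (6 residual and 5.67 prior degrees of freedom). Each later time was compared with 20 min, 6 h with 2 h and 24 h with 6 h, and an F test covered any time difference. The p-values were two-sided and Benjamini-Hochberg adjusted within each comparison, with 0.05 as the threshold. Errors of named genes are SDs of the changes of the 3 pigs. The pigs pair the arrays, as the design text says and as the values show: the deviations of the arrays from their time means correlated with r between 0.409 and 0.656 for the 18 pairs of arrays of 1 pig, and between -0.456 and -0.0386 for arrays of different pigs. As the deviations at each time cancel out, the negative correlations follow from the positive ones and are no separate evidence. Without the replicate block, 0 probe sets passed in the comparison of 24 h with 20 min, against 1 with it.

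A set of 30 gene lists was fixed before the data were examined, covering stress responses, energy metabolism, contractile and structural genes, proteolysis, RNA decay, regulators and markers of other cell types of muscle. Lists with at least 5 genes on the array, 29 of them, were tested with camera at a preset correlation of 0.01; the list of mitochondrially encoded genes had 0 genes on the array. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether a list's genes move on balance in 1 direction and does not set the list against other genes.

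The genes named were chosen by a rule fixed before the data were examined. For each comparison with 20 min these were up to 12 highest and 12 lowest genes that passed with the same sign in all 3 pigs or, where none passed, the 5 highest and 5 lowest log2 changes among the 20 smallest p; for the other comparisons 3 and 3. Up to 4 members were named per list, those past the threshold by size of change and then those with the highest mean. That the threshold is the one adjusted over the list alone was settled after seeing that almost none passed over all probe sets. The rule takes the probe set with the small p, which for several genes is not the brightest one; the brightest is then given beside it. Genes outside the rule are said to be so where they are named.

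The model was tested on simulated data with the real means and spread, 23999 probe sets and 200 changed ones, in 5 simulations of the comparison of 24 h with 20 min. It recovered 64.5% of 1.41-fold changes, 100% of 2-fold and 100% of 4-fold changes, and 6.57% of its calls were false. These rates hold for simulations with 200 changed probe sets. They cannot be carried over to the real data, where the number of true changes and their spread between pigs are not known. In the real comparison of 24 h with 20 min, 19 probe sets changed by more than 2-fold and 1 probe set passed. RNA integrity was read from the 3′ minus 5′ difference of control probe sets with an exact permutation of the times within pigs, 13824 reassignments.

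Alternatives tried were no block or a random block for pig, leaving out the dimmest 40% of probe sets, cyclic loess, centring on the brightest probe sets and repeated quantile normalisation. Others were a trended and robust prior, array weights, only the arrays of the 2 times compared, 1 probe set per gene, stricter thresholds, each pig left out, the other list tests and all probe sets of list genes. Added after the data were seen were a trend over log2 hours, the removal of 3 single arrays (20 min of pig 3, 2 h of pig 2 and 24 h of pig 3), an exact permutation of list slopes, and an estimated correlation together with arrays left out. Figures were drawn with python 3.11.15.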

Results

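Transcript abundance was measured in the semimembranosus, a large muscle of the hind leg, of 3 female pigs of a commercial hybrid of about 160 kg. Each pig gave 1 portion of muscle at each of 4 times after slaughter, 20 min, 2 h, 6 h and 24 h, while the carcass was chilled towards 4 °C. Each portion was hybridised to its own one-colour Affymetrix porcine array, so that the 12 arrays form 4 times with 3 pigs each. The array medians lay between 5.89 and 5.94 on the log2 scale after RMA, and any 2 arrays correlated across probe sets with r between 0.986 and 0.997. The 20 min arrays served all 3 comparisons with the earliest time, so those comparisons share their chance values, and the 3 pigs limit the precision of each.

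Time after death left most transcripts within narrow limits, and 1 transcript passed the test over the whole course. This was the probe set annotated to OCA2, which encodes a melanosomal membrane protein known for its part in pigmentation. The annotation dates from 2016 and was not checked against the sequences of the probe set. Its log2 level was 7.84 ± 0.83 (SD, n = 3) at 20 min, 7.04 ± 0.71 at 2 h, 6.92 ± 0.53 at 6 h and 6.45 ± 0.62 at 24 h. Of 23999 probe sets, 1 differed over the 4 times in limma's F test with pig as a block (adjusted p = 0.0388 for OCA2). An unadjusted p under 0.05 was seen at 1972, against 1199.95 that chance gives on average. Where probe sets vary together such a count can lie far from that average, so the excess is not a count of changed transcripts. The OCA2 call was lost without the replicate block, with pig as a random block, with cyclic loess and without the dimmest 40% of probe sets, each with 0 passing. It was also lost without pig 1, without pig 2, without the 2 h array of pig 2 and without the 24 h array of pig 3, each again with 0. Without pig 3, 1 other probe set passed (C1QC), and without the 20 min array of pig 3, 3 others did. In the comparison of 24 h with 20 min, the 95% interval of the change lay within 2-fold for 99.3% of the probe sets and within 1.5-fold for 93.3%.

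**Figure D1:**
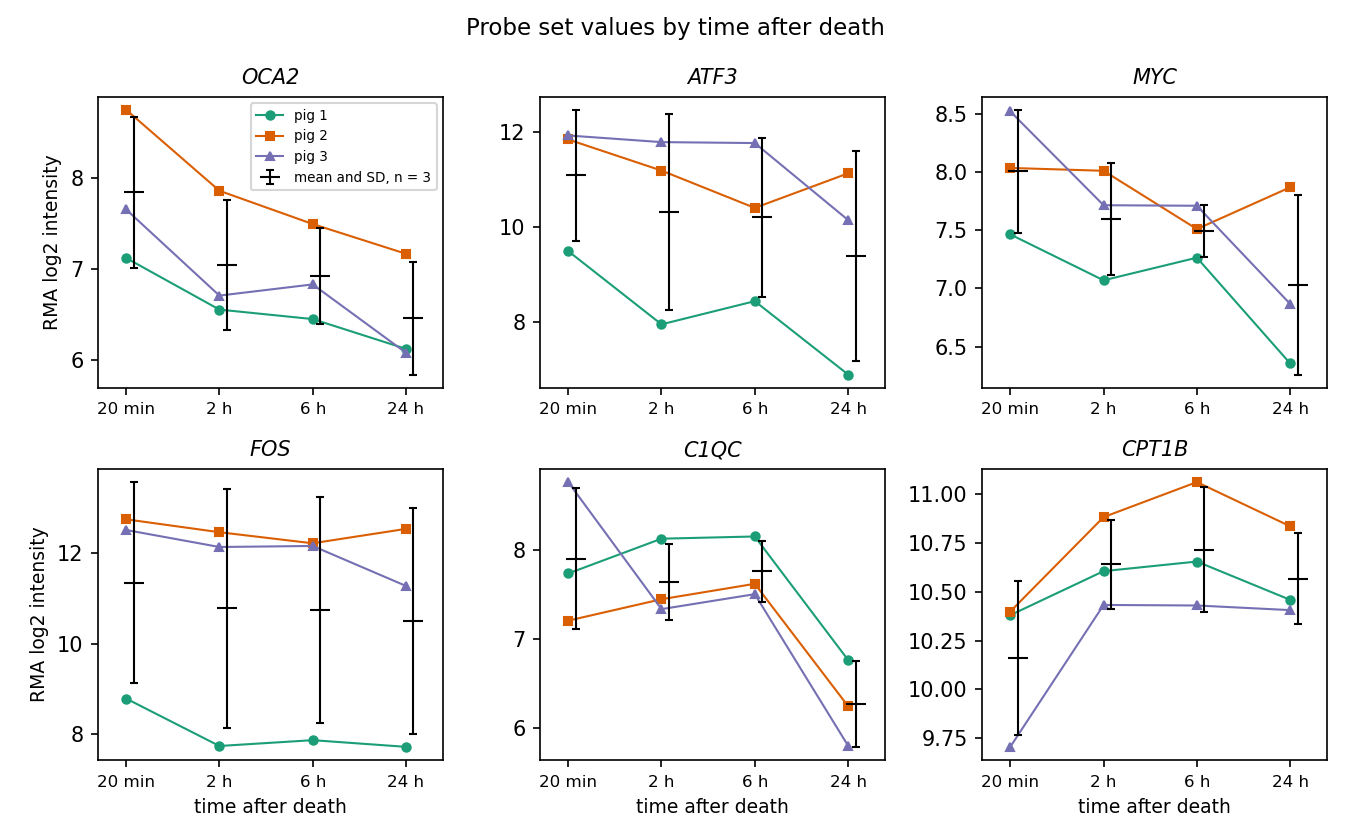
RMA log2 intensity (y axis) of the probe sets of 6 genes against time after death (x axis, 4 sampling times, evenly spaced and not to scale). Coloured lines join the arrays of each pig, and black marks give the mean and SD of the 3 pigs; OCA2 goes from 7.84 at 20 min to 6.45 at 24 h, and the FOS and ATF3 lines of pig 1 lie below those of pigs 2 and 3 throughout.

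By 24 h after death, the probe set annotated to OCA2 was 2.62-fold lower than at 20 min. As lists fixed beforehand, immediate early regulators and ribosomal protein genes were lower, and genes of oxidative metabolism and of slow fibres were higher, by camera with a preset correlation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.731). With the preset one, each of the 3 wrong groupings that part all pigs gave 7 lists, against 5 in the real one. OCA2 was lower in 3 of 3 pigs, by a log2 change of -1.39 (SE 0.126, limma adjusted p = 0.00399), and was the 1 probe set that passed. At unadjusted p under 0.05 there were 3138 probe sets, 1538 higher and 1600 lower. Over the alternative fits this count ran from 1394 without the replicate block to 3830 with array weights. It was 1681 without pig 3. A change of more than 2-fold was seen at 19 probe sets, all of them lower at 24 h. The OCA2 call was lost without the replicate block (adjusted p = 0.805), with pig as a random block (0.321), without pig 2 (0.0750), without pig 3 (0.0999) and without the 24 h array of pig 3 (0.0566). Over the alternative fits its log2 change lay between -1.58 and -1.29, and its adjusted p between 5.64e-04 and 0.805. With the arrays of these 2 times alone 0 probe sets passed; without pig 1 an unnamed probe set passed beside OCA2, and without the 20 min array of pig 3 C1QC did (-1.03, adjusted p = 0.0189).

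Immediate early and stress-response transcription regulators, which cells induce within minutes of a stimulus and whose mRNAs are short-lived, were lower at 24 h. Of the 21 on the array, 18 had a lower mean at 24 h, 12 of them in all 3 pigs, and the list mean was -0.44 ± 0.30 (SD over 3 pigs, camera adjusted p = 4.06e-05, and adjusted p = 0.731 with an estimated correlation). Adjusted over the list alone, 9 members were lower and 0 higher, and over all probe sets 0 passed. The log2 change was -1.69 ± 0.94 for ATF3, -0.97 ± 0.75 for MYC, -0.91 ± 0.99 for NR4A3 and -0.84 ± 0.55 for FOS, each as mean ± SD over 3 pigs. The list mean was -0.48 in pig 1, -0.12 in pig 2 and -0.72 in pig 3, and the 3′ minus 5′ difference of the EF1A control, a sign of RNA quality, changed by 0.38, -0.01 and 0.47 in these pigs. The list did not pass without the replicate block (adjusted p = 0.0786).

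Genes of oxidative energy metabolism were higher at 24 h. For nuclear-encoded oxidative phosphorylation, 57 of 59 genes had a higher mean, with a list mean of 0.14 ± 0.13 (SD over 3 pigs, camera adjusted p = 1.97e-11). For the citrate cycle and fatty acid oxidation 36 of 39 did, with a list mean of 0.17 ± 0.15 (camera adjusted p = 7.18e-11). With an estimated correlation, the adjusted p was 0.731 for both. Adjusted over the list alone, 11 citrate cycle and fatty acid oxidation genes were higher and 0 oxidative phosphorylation genes were, and over all probe sets 0 of either list passed. The fatty acid oxidation enzymes ACADVL and ACAA2 had log2 changes of 0.41 ± 0.40 and 0.41 ± 0.30, CPT1B, which brings fatty acids into mitochondria, 0.41 ± 0.31, and the fatty acid carrier FABP3 0.40 ± 0.41. NDUFA4 and ATP5A1, subunits of the respiratory chain and of ATP synthase, had changes of 0.21 ± 0.09 and 0.13 ± 0.10 that did not pass. The oxidative phosphorylation mean at 24 h was 0.003 above the 20 min array in pig 1, 0.16 in pig 2 and 0.25 in pig 3. Fibroblast and extracellular matrix markers were at 0.09, 0.07 and -0.42 in these pigs, and macrophage and leukocyte markers at -0.17, 0.07 and -0.65. Without the 20 min array of pig 3 the list mean was 0.0862 and without pig 3 it was 0.0831; for the citrate cycle and fatty acid oxidation these means were 0.105 and 0.102. All 4 passed camera with the preset correlation and none with an estimated one (adjusted p = 0.835 and 0.967 for oxidative phosphorylation, 0.835 and 0.931 for the citrate cycle and fatty acid oxidation).

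Slow-fibre contractile genes, which mark type I muscle fibres, were higher at 24 h in 10 of 12 cases, with a list mean of 0.13 ± 0.19 (camera adjusted p = 0.00327, and adjusted p = 0.731 with an estimated correlation). The slow myosin genes MYL2 and MYH7 had log2 changes of 0.06 ± 0.10 and 0.14 ± 0.15, and 0 members passed when adjusted over the list alone. The list mean was -0.09 in pig 1, 0.23 in pig 2 and 0.25 in pig 3. The call was lost without pig 2 (mean 0.0822, adjusted p = 0.0679) and without pig 3 (0.0728, adjusted p = 0.0535); the mean was 0.244 without pig 1 and 0.0833 without the 20 min array of pig 3. The 8 fast-fibre contractile genes did not pass as a list (mean -0.04 ± 0.06, adjusted p = 0.463), and their mean was 0.0016 when the arrays were centred on the brightest probe sets. Cytosolic ribosomal protein genes were lower in 53 of 63 cases, 38 of them in all 3 pigs, with a list mean of -0.08 ± 0.03 (camera adjusted p = 1.10e-04). The list had an adjusted p = 0.731 with an estimated correlation and an adjusted p = 0.0403 in the fry rotation test, and its mean was -0.0309 when the arrays were centred on the brightest probe sets. RPS2 had a log2 change of -0.13 ± 0.07, and 0 ribosomal protein genes passed adjusted over the list alone.

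**Figure D2:**
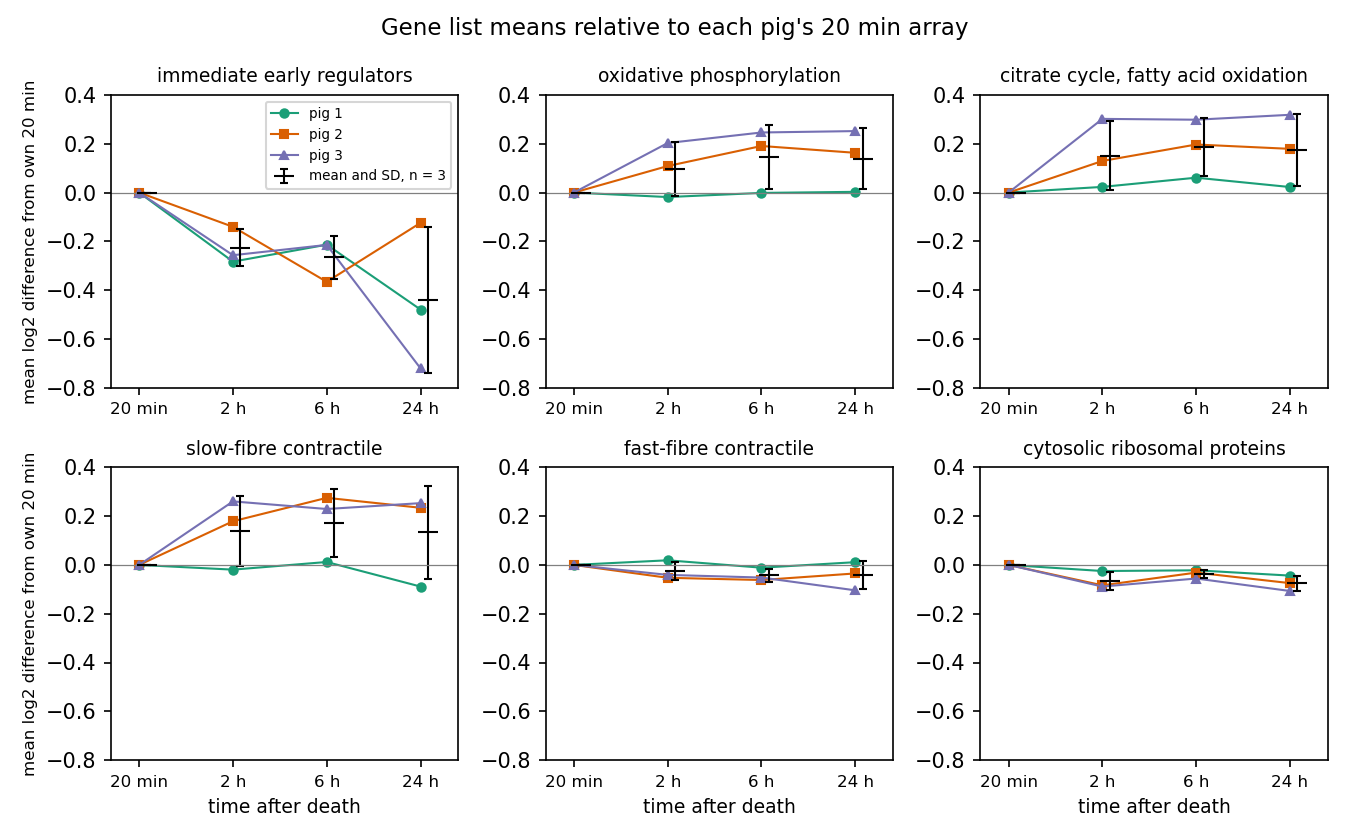
Mean log2 difference of 6 gene lists from each pig's own 20 min array (y axis) against time after death (x axis, evenly spaced and not to scale), with a line per pig and black marks for the mean and SD of 3 pigs. The immediate early list lies at -0.44 on average by 24 h, and the oxidative phosphorylation line of pig 1 stays near 0 where pigs 2 and 3 reach 0.16 and 0.25.

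The other 24 lists did not pass at 24 h, although single members stood out in several of them when adjusted over the list alone; over all probe sets 0 of these members passed. In the cytokine and inflammatory response list (mean -0.13 ± 0.15, adjusted p = 0.291), 4 of 30 genes were lower. Their log2 changes were -0.81 ± 0.81 for PTX3, -0.80 ± 0.60 for IL18, -0.65 ± 0.25 for the monocyte chemokine CCL2 and -0.47 ± 0.25 for the NF-κB inhibitor NFKBIA. The list mean was -0.0432 without pig 3 and -0.0743 without its 20 min array. Among 20 macrophage and leukocyte markers (mean -0.25 ± 0.37, adjusted p = 0.545), 3 were lower: the complement genes C1QC and C1QA at -1.63 ± 1.15 and -1.01 ± 0.80, and the scavenger receptor CD163 at -1.29 ± 0.98. Pig 3 had the lowest changes, with -2.96 for C1QC, -1.94 for C1QA and -2.41 for CD163. Without its 20 min array the list mean was -0.0746, C1QC changed by -1.03 and C1QA by -0.57, and without pig 3 the list mean was -0.0453. Of 19 myogenic regulators (mean -0.12 ± 0.14, adjusted p = 0.488), 3 were lower: MSTN, which encodes the growth inhibitor myostatin, at -1.03 ± 0.65, MYF6 at -0.50 ± 0.42 and MEF2A at -0.31 ± 0.07. Their list mean was -0.0427 without pig 3 and -0.0834 without its 20 min array. The stretch-responsive ANKRD1 was lower by -1.34 ± 0.89 in the sarcomere scaffold and Z-disc list (mean -0.07 ± 0.09, adjusted p = 0.921), with TTN at 0.09 ± 0.02.

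Stress and proteolysis lists gave few single genes at 24 h. Among 27 heat shock proteins and cochaperones (mean -0.07 ± 0.02, adjusted p = 0.223), the small heat shock protein gene HSPB6 was higher by 0.71 ± 0.43 and HSPH1 lower by -0.39 ± 0.14. In the endoplasmic reticulum and integrated stress response list (mean -0.12 ± 0.10, adjusted p = 0.0670), the transcription factor gene XBP1 was lower by -0.33 ± 0.12. This list passed without pig 3 (mean -0.15, adjusted p = 0.0067), without its 20 min array (-0.15, adjusted p = 0.00852), without its 24 h array (-0.13, adjusted p = 0.0119) and in 3 other alternatives. Over the alternatives its adjusted p ranged from 0.00184 to 0.731. The heat shock list passed without pig 3 (-0.07, adjusted p = 0.0428) and without its 20 min array (-0.09, adjusted p = 0.0332). Neither of these 2 lists passed in these fits with an estimated correlation (adjusted p = 0.931 without pig 3, 0.835 without its 20 min array and 0.784 without its 24 h array). GADD45A and TNFRSF12A were lower by -0.67 ± 0.20 and -0.52 ± 0.40 (24 apoptosis and p53-response genes, adjusted p = 0.488), and MT-2B and GPX1 by -0.48 ± 0.26 and -0.33 ± 0.12 (30 metallothionein and antioxidant genes, adjusted p = 0.924). Of 17 genes of calpains, cathepsins and their inhibitors, which take part in post mortem proteolysis, LGMN was lower by -0.35 ± 0.09, while CAPN3 at -0.15 ± 0.12 did not pass (list mean -0.10 ± 0.15, adjusted p = 0.223). With all probe sets of its genes this list passed (-0.16, adjusted p = 0.00561), as did mRNA deadenylation and decay (-0.07, adjusted p = 0.0351); over the alternatives their adjusted p reached 0.961 and 0.731. Of the calcium handling genes, CAMK2D was lower by -0.27 ± 0.10 (list adjusted p = 0.921). The proteasome list (33 genes, adjusted p = 0.223), the muscle atrophy and autophagy list (23 genes, adjusted p = 0.777), hypoxia response (19 genes, adjusted p = 0.178), glycolysis and glycogen metabolism (25 genes, adjusted p = 0.223) and mRNA deadenylation and decay (25 genes, adjusted p = 0.178) had 0 members past the threshold.

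Markers of other cell types did not pass as lists at 24 h, and for some the pigs differed widely. The adipocyte list (18 genes, adjusted p = 0.921) had 2 higher genes, PNPLA2 at 0.45 ± 0.30 and LPL at 0.43 ± 0.38, and 2 lower ones, ADIPOQ at -0.99 ± 1.05 and ELOVL6 at -0.61 ± 0.72. In the smooth muscle and pericyte list (10 genes, adjusted p = 0.425) SMTN and RGS5 were higher by 0.39 ± 0.21 and 0.31 ± 0.21. Fibroblast and extracellular matrix markers (23 genes, adjusted p = 0.345), endothelial markers (14 genes, adjusted p = 0.299), erythroid and blood markers (5 genes, adjusted p = 0.488), nerve and neuromuscular junction markers (5 genes, adjusted p = 0.560) and circadian clock genes (8 genes, adjusted p = 0.488) gave 0. Without pig 3, endothelial (0.14) and smooth muscle (0.14) markers passed as higher (adjusted p = 0.0067 for both), as they did without its 24 h array (0.14 and 0.11, adjusted p = 0.00417 and 0.0328). In that fit without pig 3, fibroblast markers passed as higher (0.0833, adjusted p = 0.0245), whereas they passed as lower without pig 1 (-0.17, adjusted p = 0.0287). With an estimated correlation 0 lists passed in any fit with arrays left out (smallest adjusted p = 0.633). Among 20 candidate reference genes for quantitative PCR (adjusted p = 0.223), GAPDH and ACTG1 included, 0 passed adjusted over the list alone. The median, the mean and the test of a list differed in sign for 4 of the lists that did not pass and for 0 that did.

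At 2 h, 0 probe sets passed (smallest limma adjusted p = 0.473), with 1908 at unadjusted p under 0.05, 962 higher and 946 lower. Without the 2 h array of pig 2, 1 unnamed probe set passed. None of the genes named next passed. Among the 20 genes with a symbol and the smallest p, the lowest log2 changes were those of the immediate early gene EGR1 (-0.90 ± 0.53), EF1ALPHA (-0.88 ± 0.33; its brightest probe set changed by -0.17), the lysosomal protease gene CTSC (-0.87 ± 0.32; brightest probe set -0.09), the cysteine-degrading enzyme gene CDO1 (-0.80 ± 0.65) and OCA2 (-0.80 ± 0.20), all as mean ± SD over 3 pigs and all lower in 3 of 3. The highest of these 20 were HSPB6 (0.70 ± 0.48), AKR1CL1 (0.48 ± 0.13), CPT1B (0.48 ± 0.25), GGTA1P (0.43 ± 0.22; brightest probe set 0.30) and CDCA7L (0.38 ± 0.06), higher in 3 of 3 pigs.

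Of 29 gene lists at 2 h, 6 passed camera with a preset correlation, and 0 with an estimated one (adjusted p = 0.789 for each of the 6). Citrate cycle and fatty acid oxidation genes were higher in 35 of 39 cases (list mean 0.15 ± 0.14, adjusted p = 3.53e-10), and adjusted over the list alone 2 of them were, CPT1B and the malate dehydrogenase gene MDH2 (0.36 ± 0.21). Oxidative phosphorylation genes were higher in 53 of 59 (0.10 ± 0.11, adjusted p = 2.07e-07), slow-fibre contractile genes in 10 of 12 (0.14 ± 0.14, adjusted p = 6.19e-04) and endothelial markers in 11 of 14 (0.11 ± 0.08, adjusted p = 0.0226). Ribosomal protein genes were lower in 58 of 63 (-0.07 ± 0.04, adjusted p = 5.09e-05) and immediate early regulators in 19 of 21 (-0.23 ± 0.08, adjusted p = 0.0108), with EGR1 the 1 member that passed adjusted over the list alone. In pigs 1, 2 and 3 the oxidative phosphorylation mean was -0.02, 0.11 and 0.20, the slow-fibre mean -0.02, 0.18 and 0.26, the fibroblast mean 0.13, -0.09 and -0.35, and the macrophage and leukocyte mean 0.12, 0.14 and -0.28. The EF1A 3′ minus 5′ difference, a sign of RNA quality, changed by 0.08, 0.49 and 0.26 at 2 h in pigs 1, 2 and 3, and the immediate early mean by -0.28, -0.14 and -0.26. In the remaining lists HSPB6 and LPL (0.52 ± 0.28) passed adjusted over the list alone, and over all probe sets 0 list members passed. The immediate early call was lost without the replicate block (adjusted p = 0.407), with pig as a random block (0.310), without pig 1 (0.0772) and without the 20 min array of pig 3 (0.122). The endothelial call was lost without pig 2 (mean 0.0745, adjusted p = 0.156) and without the replicate block (0.0618). Without pig 3 the means were 0.0453 for oxidative phosphorylation, 0.0773 for the citrate cycle and fatty acid oxidation and 0.0798 for slow fibres, and without its 20 min array they were 0.0447, 0.0836 and 0.0904; without pig 1 the first and last were 0.156 and 0.220. Lists that passed at 2 h with arrays left out were macrophage and leukocyte markers (0.13 without pig 3, adjusted p = 0.0104; 0.17 without its 20 min array, adjusted p = 0.00143) and endoplasmic reticulum stress (-0.10, adjusted p = 0.0286 and 0.0326 in these 2 fits). The proteasome list (-0.05 without pig 3, adjusted p = 0.0324) and fibroblast markers (-0.22 without pig 1, adjusted p = 0.00313) did so too. With an estimated correlation 0 lists passed in any fit with arrays left out (smallest adjusted p = 0.698). With all probe sets the slow-fibre mean was 0.0892, and endoplasmic reticulum stress passed (-0.10, adjusted p = 0.0130).

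At 6 h, 0 probe sets passed (smallest limma adjusted p = 0.276, for OCA2), with 2119 at unadjusted p under 0.05, 1029 higher and 1090 lower. None of the genes named next passed. At 6 h, too, of the 20 genes with a symbol and the smallest p, the lowest log2 changes were those of single probe sets of CTSC (-0.99 ± 0.55), OCA2 (-0.92 ± 0.30), EF1ALPHA (-0.68 ± 0.35), the Mediator subunit gene MED4 (-0.65 ± 0.35) and C9H1orf21 (-0.64 ± 0.20), each lower in 3 of 3 pigs. The brightest probe sets of these genes other than OCA2, which has 1, changed by -0.10 for CTSC, -0.10 for EF1ALPHA, -0.19 for MED4 and 0.10 for C9H1orf21. TM9SF4 (0.60 ± 0.21), CPT1B (0.55 ± 0.24), the SUMO protease gene SENP2 (0.53 ± 0.19), AKR1CL1 (0.50 ± 0.25) and LOC100524391 (0.43 ± 0.09) were the highest of these 20, in 3 of 3 pigs. The brightest probe set changed by 0.15 for TM9SF4 and by -0.08 for SENP2. With array weights OCA2 passed at 6 h (log2 change -0.999), and over the alternatives its adjusted p ranged from 0.0482 to 0.999.

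Of the gene lists at 6 h, 6 passed camera with a preset correlation and 0 with an estimated one (adjusted p = 0.875 for each of the 6). Oxidative phosphorylation genes were higher in 59 of 59 cases (list mean 0.15 ± 0.13, adjusted p = 1.37e-13) and citrate cycle and fatty acid oxidation genes in 35 of 39 (0.19 ± 0.12, adjusted p = 1.37e-13). Of the latter, 5 passed adjusted over the list alone, among them CPT1B, MDH2 (0.38 ± 0.10), ECI1 (0.35 ± 0.27) and the fatty acid-sensing nuclear receptor gene PPARA (0.32 ± 0.22). In pigs 1, 2 and 3 the oxidative phosphorylation mean was -0.001, 0.19 and 0.25, the fibroblast mean 0.16, 0.02 and -0.42, and the macrophage and leukocyte mean 0.19, 0.32 and -0.28. Slow-fibre genes were higher in 11 of 12 (0.17 ± 0.14, with 0.01 in pig 1, 0.27 in pig 2 and 0.23 in pig 3, adjusted p = 3.22e-04) and endothelial markers in 13 of 14 (0.14 ± 0.16, adjusted p = 0.00776). Immediate early regulators were lower in 19 of 21 (-0.26 ± 0.09, adjusted p = 5.08e-04) and ribosomal protein genes in 50 of 63 (-0.04 ± 0.02, adjusted p = 0.0278). In the remaining lists HSPB6 (0.70 ± 0.45), CAMK2B (0.27 ± 0.06), SMTN (0.40 ± 0.24) and RGS5 (0.32 ± 0.13) passed adjusted over the list alone, and over all probe sets 0 members did. The immediate early call was lost without the replicate block (adjusted p = 0.127) and with pig as a random block (0.0539), and the endothelial one without pig 2 (mean 0.0502, adjusted p = 0.209). The ribosomal call was lost without pig 2 (mean -0.0389, adjusted p = 0.110), without pig 3 (-0.0268, adjusted p = 0.319) and without the 20 min array of pig 3 (-0.0241, adjusted p = 0.193), and its mean was -0.0679 with all probe sets. The slow-fibre mean was 0.110 with all probe sets. Without the 20 min array of pig 3 the means were 0.0922 for oxidative phosphorylation and 0.117 for the citrate cycle and fatty acid oxidation. The oxidative phosphorylation mean was 0.0948 without pig 3 and 0.219 without pig 1, and the endothelial mean 0.213 without pig 1. Macrophage and leukocyte markers passed as higher without pig 3 (0.25, adjusted p = 2.29e-06) and without its 20 min array (0.25, adjusted p = 2.80e-06). Fibroblast markers passed as lower without pig 1 (-0.20, adjusted p = 0.00176) and without pig 2 (-0.13, adjusted p = 0.0432), and as higher without pig 3 (0.0907, adjusted p = 0.0217). With an estimated correlation 0 lists passed in any fit with arrays left out (smallest adjusted p = 0.725).

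Between 2 h and 6 h, transcript levels differed little. In limma 0 probe sets passed (smallest adjusted p = 0.9997), and 542 had an unadjusted p under 0.05, fewer than the 1199.95 that chance gives on average. Of the 20 genes with a symbol and the smallest p, the lowest log2 changes, none of which passed, were -0.39 ± 0.29 for FCF1, -0.38 ± 0.12 for MYO10 and -0.38 ± 0.14 for RANBP1. The highest of these 20, which did not pass either, were 0.39 ± 0.16 for CYP39A1, 0.39 ± 0.21 for HIF1A, the hypoxia-inducible factor gene, and 0.37 ± 0.19 for CDH1. For genes with several probe sets these values come from a dimmer one. The brightest one changed by 0.03 for FCF1, -0.01 for MYO10, 0.09 for RANBP1, 0.03 for HIF1A and 0.15 for CDH1.

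Between 6 h and 24 h, the lowest log2 changes of the 20 genes with a symbol and the smallest p were those of C1QC (-1.49 ± 0.19) and C1QA (-1.07 ± 0.10), which encode chains of complement component C1q made largely by macrophages. Both were lower in 3 of 3 pigs, as was SLC35F5 (-0.82 ± 0.27), and KCNMB1 (0.36 ± 0.04), TGFBR1 (0.38 ± 0.13) and ZP3 (0.49 ± 0.26) were higher in 3 of 3. The brightest probe set changed by -0.11 for SLC35F5 and by 0.10 for TGFBR1. None of them passed, as 0 probe sets did in limma (smallest adjusted p = 0.533), with 1938 at unadjusted p under 0.05, 1027 higher and 911 lower. With only the arrays of these 2 times, 4 probe sets passed, all lower at 24 h: C1QC, C1QA, VSIG4, a complement receptor gene of tissue macrophages chosen here after its value was seen (-1.09), and 1 unnamed probe set. Without the 20 min array of pig 3, which is on neither side of this comparison but enters the estimate of the spread, 9 passed, C1QC among them, and without pig 3 C1QC alone did. Over the alternatives the adjusted p of C1QC ranged from 8.70e-05 to 0.9997.

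RNA integrity was read from 6 pairs of control probe sets that target the 3′ and 5′ parts of housekeeping transcripts. In the test of their 3′ minus 5′ log2 difference over the 4 times, 0 pairs passed (exact permutation of times within pigs, smallest two-sided p = 0.194, adjusted p = 0.792 for each). In 4 pairs, those of GAPDH and the first actin design, both ends lay at 13.9 or higher on arrays whose maxima begin at 14.8, near the top of the scale, where a change is hard to see. For EF1A the difference changed by 0.27 ± 0.21 at 2 h, in the same direction in 3 of 3 pigs, and by 0.08 ± 0.12 at 6 h. The largest change by 24 h was also that of EF1A, from 0.45 to 0.72 on average, or 0.28 ± 0.25 (SD over 3 pigs). Without pig 2 it was 0.42 ± 0.06 (exact p = 0.0417, the smallest that 2 pigs allow, and adjusted p = 0.250), and without pig 3 it was 0.18 ± 0.27 (exact p = 0.417). The 3 GAPDH pairs changed by 0.02 ± 0.05, 0.04 ± 0.03 and -0.02 ± 0.04, and the 2 actin pairs by 0.03 ± 0.03 and -0.06 ± 0.16. Bacterial control transcripts separated pig 1 from the other pigs at every time. The 36 poly-A control probe sets averaged 9.11 ± 0.35 (SD over 4 arrays) in pig 1, 6.25 ± 0.41 in pig 2 and 6.5 ± 0.53 in pig 3, whereas the 27 hybridization control probe sets averaged 10.21, 10.37 and 10.41. Pig and this difference cannot be told apart, and the block for pig removes what is constant within a pig from the comparisons of times. Differences between the arrays of a pig stay in them. Both kinds of control were highest at 20 min in each pig. The poly-A controls stood there at 9.47, 6.77 and 6.99 in pigs 1, 2 and 3, against 9.31, 6.12 and 6.72 at 24 h. The hybridization controls stood at 10.40, 10.50 and 10.62, against 10.16, 10.32 and 10.56. A technical difference of the 20 min arrays was not tested.

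**Figure D3:**
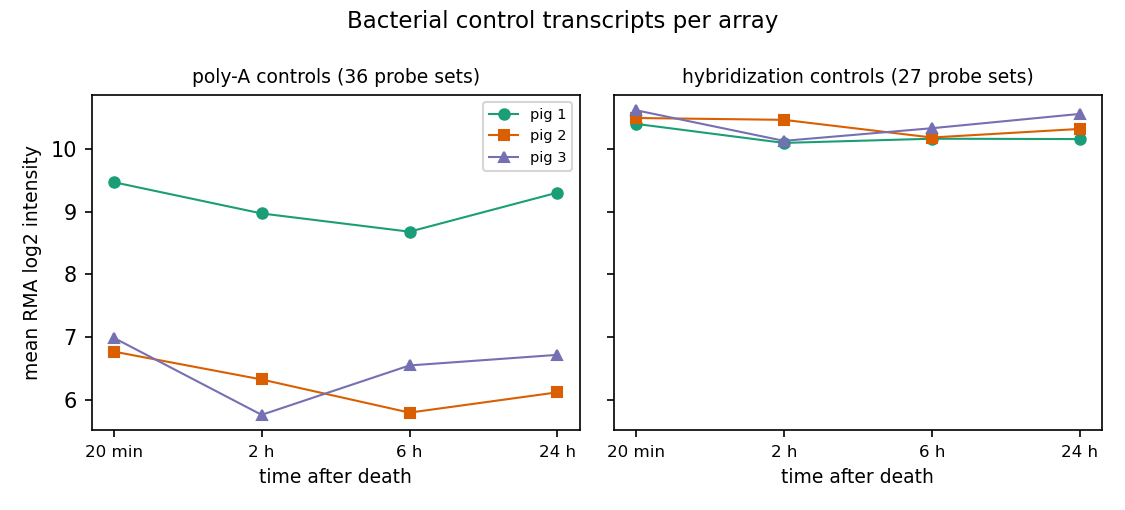
Mean RMA log2 intensity (y axis) of 36 poly-A and 27 hybridization control probe sets of bacterial and phage origin per array against time after death (x axis, evenly spaced and not to scale), with a line per pig. The poly-A controls of pig 1 average 9.11 and those of pigs 2 and 3 6.25 and 6.5, while the hybridization controls of all 3 pigs lie close together.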

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

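The tests of random lists, of fibre types and of other splits were set before their results were seen, and the other tests of this part were chosen only afterwards. Groups of 3 arrays are too small for a test of single outlying samples. The 36 poly-A control probe sets, which enter no comparison, were set apart because pig 1 exceeded the mean of pigs 2 and 3 by 2.73 on the log2 scale (6.64-fold), with its lowest array at 8.68 and the highest array of the other pigs at 6.99.

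Few probe sets passed between the times, although the muscle had been dead for up to 24 h. Changes of 2-fold or more hidden by the spread between pigs are argued against for most probe sets. The interval of the change by 24 h reached 2-fold at 0.658% of all probe sets. This does not cover those that moved most: 19 probe sets changed by more than 2-fold by 24 h, and 1 passed. C1QC, at -1.63 ± 1.15 (SD over 3 pigs), did not pass (limma adjusted p = 0.193). A halving of most transcripts relative to the labelled total RNA, which RMA would hide, would raise the dap poly-A controls by about 1 on the log2 scale against the hybridization controls. They changed by -0.18 ± 0.32 at 24 h (SD over 3 pigs), after -0.46 ± 0.36 at 2 h and -0.48 ± 0.34 at 6 h. The controls thus moved between the times in the direction opposite to that of a halving, so they are a rough measure. A loss of mRNA and total RNA alike stays open, as does the amount of control added per sample, which the labels do not give. Over the 4 times, none of 99 other assignments of times within pigs gave a passing probe set, against 1 in the real one (1 of 100), so chance is argued against for that count.

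Immediate early regulators were lower at 24 h, by -0.44 on average. Genes of like mean level did not fall as far in any of 10000 random lists, the lowest of which had a mean of -0.17. The random lists were matched on mean level alone, not on spread or on how far genes vary together. The estimated correlation within this list was 0.26, so the random lists cannot decide whether shared variation gave the fall. The fall was not seen in pig 3 alone: the list mean was -0.48 in pig 1, -0.12 in pig 2 and -0.72 in pig 3. Of the 21 members, 12 were lower in all 3 pigs. Without pig 3 the mean was -0.30, and the list passed camera with a preset correlation (adjusted p = 0.0109). Neither form of camera can decide this. The preset correlation of 0.01 lies far below the 0.26 estimated for this list. With an estimated correlation (adjusted p = 0.931) the list did not pass, but it did not with all 3 pigs either (adjusted p = 0.731). Whether the fall in pigs 1 and 2 exceeds chance stays open. Broken RNA stays open: the EF1A 3′ minus 5′ difference changed by 0.27 ± 0.21 at 2 h, 0.08 ± 0.12 at 6 h and 0.28 ± 0.25 at 24 h, and 4 of the 6 control pairs lie near the top of the scale. At 24 h it changed by 0.38 in pig 1, -0.01 in pig 2 and 0.47 in pig 3, where pig 2 had the smallest fall of the list. This order did not recur earlier. At 6 h EF1A changed by 0.06, -0.04 and 0.21 in pigs 1, 2 and 3, and the list mean by -0.21, -0.37 and -0.21. At 2 h pig 2 had the largest EF1A change (0.49) and the smallest fall (-0.14). Chance in the order of the times stays open too, since the exact permutation p of the slope of the list mean was 0.0072 and 0.0692 after adjustment over the 29 lists, as does decay of unstable mRNAs, a candidate explanation that was not tested.

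Oxidative phosphorylation and slow-fibre genes were higher after 20 min in pigs 2 and 3 and not in pig 1. The 20 min array of pig 3 is not the only source. The oxidative phosphorylation mean of pig 2, set against its own 20 min array, was 0.11, 0.19 and 0.16 at 2 h, 6 h and 24 h. Without the 20 min array of pig 3 the mean at 24 h was 0.0862 in place of 0.14, and the list passed camera with a preset correlation (adjusted p = 8.98e-06). Here too neither form of camera can decide. The preset correlation of 0.01 lies far below the 0.48 estimated for this list. With an estimated correlation (adjusted p = 0.835) the list did not pass, but it did not with all arrays either (adjusted p = 0.731). How much of the rise rests on single 20 min arrays stays open. Portions that held more slow oxidative fibres are a candidate explanation: beyond the means of pig and time, both lists moved the same way in 11 of 12 arrays (one-sided permutation p = 7.7e-04, the smallest that 1296 permutations can give), and fast-fibre genes the opposite way to slow-fibre genes in 8 of 12 (p = 0.058). The time after death stays open beside it, with an exact slope p of 0.0056 for oxidative phosphorylation and 0.0692 after adjustment, as does a change in other cells of the portions, which was not tested: fibroblast markers stood at -0.42 in pig 3 at 24 h. With the means of pig and time taken out, the values of the 12 arrays are not independent. Another factor that moves both lists alike could give the same result. The fibre explanation was found and tested on the same arrays, so it is a hypothesis.

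The splits of the 6 arrays of 2 times number 10 with the real one, too few for a share under 0.05, and 3 of the 9 others part the arrays of all 3 pigs as the real one does. For probe sets the real split and the highest other gave 0 and 7 at 2 h, 0 and 0 at 6 h, 1 and 0 at 24 h, 0 and 0 for 6 h against 2 h, and 0 and 0 for 24 h against 6 h. The 7 came from 1 split that does not part all pigs, while the 5 remaining splits of that kind at 2 h gave 0. At least as many calls as in the real split came from 10, 10, 1, 10 and 10 of the 10 splits in that order, the real one included. For gene lists the real split and the highest other gave 6 and 6 at 2 h, 6 and 6 at 6 h, and 5 and 9 at 24 h, with as many lists or more in 3, 2 and 8 of the 10 splits. The 3 other splits that part all pigs gave 1, 1 and 6 lists at 2 h, 3, 3 and 6 at 6 h, and 7, 7 and 7 at 24 h. At 24 h each of them gave more lists than the 5 of the real split. The number of lists called there with the preset correlation is thus no higher than wrong groupings gave.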

How the results depend on the processing

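The log2-hours trend, the removal of single arrays and the estimated correlation with arrays left out were chosen after seeing the data. Under the alternatives, 126 of 177 counts stayed within 1.5 times their value. Of 454 values of 33 named results, 445 kept direction and side of the threshold, 5 lost and 4 gained a call. Only OCA2 at 24 h passed in the main fit, so no other named gene could lose a call, and the 5 losses were all its own. For the 3′ over 5′ controls, 24 of 24 changes moved by less than 1 SD. Of 1476 list means, 1372 stayed, 48 lost and 26 gained a call, 28 moved by over 1 SD without a call and 2 reversed. Most of these values could not lose a call either, as 6, 6 and 5 of 29 lists passed at 2 h, 6 h and 24 h in the main fit. Over the 4 times, 0 probe sets passed at adjusted p under 0.01, without the replicate block, with a random block, without the dimmest 40% and with cyclic loess, and 2 with the log2-hours trend (OCA2 and an unnamed set); leaving out arrays gave 0 to 3. At 24 h, 0 passed with only the 2 times' arrays, without the replicate block and with a random block; leaving out gave 0 to 2. Against 6 h, 24 h gave 4 with only the 2 times' arrays and 0 to 9 with arrays left out. At 6 h array weights gave 1, and at 2 h leaving out gave 0 to 1, the 1 without the 2 h array of pig 2. With an estimated correlation 0, 0 and 0 lists passed at 2 h, 6 h and 24 h, and 0 with arrays left out as well, with fry 0, 0 and 1; with all probe sets 8 passed at 24 h, and leaving out with the preset correlation gave 4 to 9, the highest without pig 3 and 8 without its 24 h array. Fibroblast and matrix markers, which did not pass, turned from -0.20 to 0.0907 at 6 h and from -0.17 to 0.0833 at 24 h between the lowest and highest fits with a pig left out, passing as lower without pig 1 and as higher without pig 3. The cause of these shifts was not tested, and leaving out arrays raised some counts and lowered others. Dim probe sets lie near background, where changes read too small.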

Other observations

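Some genes known from macrophages had lower values at 24 h than at 6 h in 3 of 3 pigs. They were chosen after their values were seen, as was C4BPA (-1.63 ± 0.56), which encodes a complement regulator, and none passed the test over all probe sets. The log2 change was -1.49 ± 0.19 (SD over 3 pigs) for C1QC, -1.11 ± 0.45 for CD163, -1.09 ± 0.07 for VSIG4, -1.07 ± 0.10 for C1QA, -0.75 ± 0.26 for MRC1 and -0.74 ± 0.24 for FCGR2B (limma adjusted p between 0.533 and 0.589). C1QC stood at 7.74, 7.21 and 8.77 at 20 min in pigs 1, 2 and 3, at 8.16, 7.63 and 7.51 at 6 h, and at 6.77, 6.25 and 5.81 at 24 h. The macrophage and leukocyte list gave a mean of 0.25 at 6 h against 20 min without pig 3 (camera adjusted p = 2.29e-06, and adjusted p = 0.872 with an estimated correlation). With all pigs it was 0.08 ± 0.32 and did not pass. At 24 h against 20 min 9 of its 20 genes were higher, and it did not pass (adjusted p = 0.545).

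The pigs differed from each other far more than the times did. In the same model, 4770 probe sets (19.9%) differed between pigs: 3083 between pigs 2 and 1, 2636 between pigs 3 and 1, and 2705 between pigs 3 and 2. FOS was higher in pig 2 than in pig 1 by 4.46 and in pig 3 by 3.99 on the log2 scale (SE 0.173), ATF3 by 2.94 and 3.21, EGR1 by 2.83 and 2.4, and the stress-inducible HSPA6 by 2.98 and 2.15. CYR61 and BTG2 were higher in pig 2 than in pig 1 by 3.41 and 2.92. The matrix gene THBS2 was higher in pig 3 than in pig 1 by 3.06 and than in pig 2 by 3.49, and SMPDL3A was lower in pig 3 than in pig 2 by -3.06. Pig 1, with low immediate early transcripts, is the pig with high poly-A controls, and with 1 pig on each side the animal and its handling in the laboratory cannot be told apart.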
